A study of Mus musculus with 2 samples.

How the data were processed

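Single-cell RNA sequencing was performed on tumours grown from MC38 cells, a mouse colorectal cancer line, and taken 21 days after engraftment. There were 2 libraries, 1 from tumours of vector control cells and 1 from tumours of cells in which TMEM16F, the product of the gene Ano6, had been knocked out, per the labels. The number of mice behind a library is not given in the sources used here. Libraries were made with the 10x Genomics 3′ droplet chemistry, per the labels' protocols. Because this chemistry reads the 3′ end of a transcript, it can still count RNA of a gene whose coding sequence has been interrupted upstream.

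The deposited matrices hold whole UMI counts per gene and cell barcode, with no normalisation, and were written by Cell Ranger 8.0.0, per the file headers. The genome build was mm10 and Seurat 3.1.1 was among the tools, per the submitters' processing notes. The gene annotation and the step at which Seurat was used are not given in the sources used here. Each matrix lists 34290 genes. The vector control library held 5253 barcodes with 46338994 UMIs (median 6236 UMIs and 2010 genes per barcode, lowest total 506 UMIs). The TMEM16F KO library held 5993 barcodes with 49777630 UMIs (median 6193 UMIs and 2053 genes per barcode, lowest total 500 UMIs). The study states 10782 cells of 14 types. The files hold 11246 barcodes and the filter used here kept 10716 of them.

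A barcode was kept with at least 200 genes and under 20% mitochondrial UMIs. The mitochondrial limit removed 4 barcodes of the vector control and 18 of the TMEM16F KO library, of which 1 in each also had too few genes. Doublets were scored with Scrublet, as implemented in scanpy, within each library. Its automatic threshold marked 3 of 5993 and 0 of 5253 barcodes and so did not work on these data. Instead, the barcodes with the highest scores were left out at a rate of 0.8% per 1000 barcodes of a library, which removed 221 vector control and 287 TMEM16F KO barcodes. The kept cells numbered 5028 (median 6019.5 UMIs) and 5688 (median 5995 UMIs). In the vector control library 20.5% of them had under 2000 UMIs, against 14.6% in the TMEM16F KO library.

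The UMIs of each cell were scaled to 10000 and log-transformed. The libraries were clustered together on 2000 variable genes, 30 principal components, 15 neighbours, a shared-neighbour graph with Jaccard weights and the Leiden algorithm at resolution 1 (seed 1). Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin variable and T cell receptor variable genes were kept out of the variable genes, and no batch correction was applied. This used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9, with matplotlib 3.10.9 for the plots.

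Clusters were named from marker lists. A marker's level in a cluster was divided by its level in the cluster with the highest level, and these values were averaged over the markers of a lineage. A name needed a mean of at least 0.2, a lead of 0.03 over the next lineage or of 3 markers among the 10 leading genes, and at least 3 markers seen in 25% of the cells. A cluster stayed unnamed if its leading genes held more markers of another lineage. It also stayed unnamed if its median UMI count was under 1 part in 3 of the library's with fewer than 2 own markers leading, or if T cell and macrophage markers stood together at a relative level of 0.15. Within T cells and mononuclear phagocytes a subtype needed a level of 0.25 and a lead of 0.05. Its name also fell if the 10 leading genes against all other cells held more markers of another class. Clusters that did not meet these rules are called other T-like and unresolved phagocyte-like. These naming thresholds were set after the data had been seen, and the names were rebuilt here, so a difference from the study may come from them. Clusters left unnamed were cluster 5 (78 TMEM16F KO and 645 vector control cells, with a median of 1128 UMIs) and cluster 14 (80 and 133 cells with T cell and macrophage markers together). Together they made up 2.78% of the kept TMEM16F KO cells and 15.5% of the kept vector control cells. Leukocyte-like cells, the base of the main shares, are all kept cells outside the unnamed clusters and the stroma-like cluster 15 (80 and 99 cells). They numbered 5450 in the TMEM16F KO and 4151 in the vector control library.

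With 1 library per group there is no replicate, so no test was run and the difference between the libraries cannot be separated from a difference between tumours or cell preparations. Shares of cells have exact Clopper-Pearson intervals, summed UMIs exact Poisson intervals, and ratios exact conditional binomial intervals, all at 95%. Intervals and floors cover counting error only, so they can be too narrow where the UMIs of a gene sit in few cells. Expression was compared in classes with at least 50 cells in each library, as CPM of the UMIs summed over the cells of a class, in which every sum is scaled to the same total. A ratio against a sum of 0 is given as a lower bound at a floor of 3 counts per library. Genes are named by a rule of size. In each class, the 5 genes with the highest and the 5 with the lowest log2 ratio of CPM + 10 were taken among genes with at least 50 UMIs over both libraries and a UMI in at least 5% of the class's cells in the library where the gene was higher. The ratio had to be at least 2-fold with an interval that excludes 1, and the CPM at least 0.5 times that of the cells outside the class. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin variable, T cell receptor variable, Xist, Y-linked and predicted genes were left out. In addition, up to 4 members with most UMIs are named of each gene list described, and Ano6 is always named. For a gene list the median log2 ratio of its members with at least 50 UMIs is given. Its interval comes from 2000 Poisson redraws of the counts, and its percentile is among 10000 random lists of the same size matched on mean expression. The percentile describes these libraries only. Scaling by trimmed means, or without mitochondrial, ribosomal protein and haemoglobin genes, moved the median log2 ratio of all genes by less than 0.1 in every class.

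Intervals marked as from redrawn cells come from 2000 draws of whole cells within each library, a choice made after seeing the data. Shares of cells with a UMI are given after thinning each cell to 3182 UMIs, with unthinned values marked as such. Thinning left out 1562 of 5028 vector control and 1422 of 5688 TMEM16F KO cells, which were shallower. Gene positions are from the GENCODE annotation of the mm10 build, matched by gene identifier for 43 of 43 genes. The list symbols Aldoa, Ero1l, Atp5a1, Atp5b, Atp5e and Atp5g1 matched no gene name in the files and were not used.

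The ratio, naming and list steps were tested on simulated counts drawn from the pooled profile of a class, with genes changed by 1.5-, 2- and 4-fold. All simulated cells of a library shared 1 profile with Poisson counts. The simulation therefore cannot tell how the intervals hold where cells of a class differ from each other. For CD8 T-like cells (9391 genes), 95.7% of the intervals held the simulated ratio, and the interval lay on the simulated side of 1 for 81.4% of the genes changed by 1.5-fold, 96.9% of those changed by 2-fold and 100% of those changed by 4-fold. For NK-like cells (5935 genes) the values were 96.1%, 57.0%, 91.9% and 100%. All 10 genes named in each simulated class had been changed. Among unchanged genes, 10 in CD8 T-like and 18 in NK-like cells still passed 2-fold with an interval that excludes 1.

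The groups, the cell filter, the doublet rate, the clustering settings, the marker lists, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives changed the filter (at least 500 genes and under 10% mitochondrial UMIs, or none), the doublet rate, the resolution (0.5 or 2), the number of variable genes (1000 or 4000), the clustering of the libraries apart, classes from the marker UMIs of single cells, the denominator, thinning before clustering, the scaling (without mitochondrial, ribosomal protein and haemoglobin genes, or by trimmed means of M values), the pseudocount (1 or 50 CPM), the minimum of 10 UMIs and a mean over cells in place of a sum. Alternatives chosen after seeing the data were a minimum of 2000 UMIs per cell, counting cluster 5 as macrophage-like, leaving out the cycling macrophage-like cluster, weighting the clusters of a class alike in both libraries, and leaving the gene with most UMIs out of each of the M1 and M2 lists. Neutrophil-like, pDC-like and B-lineage-like cells were too few for a comparison of expression.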

Results

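Tumours grown from MC38 cells, a mouse colorectal cancer line, were compared 21 days after engraftment to ask how the tumour's immune cells differ when the engrafted cells lack TMEM16F. TMEM16F is a calcium-activated phospholipid scramblase that moves phosphatidylserine to the outer face of the plasma membrane, and its gene is Ano6. There was 1 single-cell library from vector control tumours and 1 from TMEM16F KO tumours, so no difference between them has a replicate check. The vector control library gave 5028 kept cells out of 5253 barcodes (46338994 UMIs) and the TMEM16F KO library 5688 out of 5993 (49777630 UMIs). All intervals are 95% intervals for counting error only, and values are for the TMEM16F KO library against the vector control library.

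Ano6 (ENSMUSG00000064210, chromosome 15, positions 95790843 to 95974751, plus strand, mm10) was read in both libraries. Over all kept cells it stood at 33.3 CPM (31.6 to 35.0; 1527 UMIs) in the TMEM16F KO library and at 28.7 CPM (27.1 to 30.4; 1235 UMIs) in the vector control library, a ratio of 1.16 (1.08 to 1.25). Macrophage-like cells held most of its UMIs, at 51.7 against 41.3 CPM. Stroma-like cells, led by Sparc, Bgn and Col1a1, had 57.4 against 65.1 CPM, a ratio of 0.882 (0.647 to 1.19). After thinning, 8.39% against 7.82% of all cells had an Ano6 UMI (unthinned 18.5% against 16.1%). The deletion was made in the engrafted tumour cells, and no cluster could be named tumour-like. The epithelial keratin transcripts among the fixed tumour markers were close to absent, with 1 Krt8 UMI in the TMEM16F KO library, 0 in the vector control library and 0 of Krt19 in either. In the 66 TMEM16F KO and 112 vector control cells with UMIs of at least 2 of the 14 tumour markers, Ano6 stood at 28.0 against 32.7 CPM, a ratio of 0.856 (0.561 to 1.28). The group labels could therefore not be checked in tumour cells, and a 3′ count can persist after a deletion.

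Mononuclear phagocytes were the largest part of the infiltrate in both libraries, followed by CD8 T-like cells, and the shares of NK-like and neutrophil-like cells were higher in the TMEM16F KO library, the former not in every clustering. NK-like cells, innate lymphocytes that kill without a rearranged receptor, made up 5.52% (4.93 to 6.16; 301 cells) of leukocyte-like cells against 3.18% (2.67 to 3.76; 132 cells), a ratio of 1.74 (1.41 to 2.15), with NK cell markers near level inside the class (median log2 ratio -0.056). Other T-like cells, led by Tcf7 and Lef1, numbered 327 against 196, a ratio of shares of 1.27. Neutrophil-like cells made up 0.881% (48 cells) against 0.458% (19 cells), a ratio of 1.92 (1.11 to 3.47). The share of CD8 T-like cells was 18.8% (17.8 to 19.9) against 18.3% (17.1 to 19.5), that of Treg-like cells 5.91% against 5.76%, and that of macrophage-like cells 31.9% against 32.4%, each within counting error. Monocyte-like cells, at 1.01% against 1.30%, also differed by less than counting error. Unresolved phagocyte-like cells (clusters 0 and 3), which met the naming rule for neither macrophage-like nor monocyte-like cells, were lower in the TMEM16F KO library, at 24.1% against 27.4%, a ratio of 0.880 (0.812 to 0.954). All mononuclear phagocytes together stood at 57.0% against 61.1% of leukocyte-like cells, and all T cells at 30.7% against 28.8%.

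These shares depend on how low-UMI barcodes are treated, because cluster 5, which stayed unnamed, held 12.8% of the kept vector control cells and 1.37% of the kept TMEM16F KO cells. Cluster 14, with T cell and macrophage markers in 1 cluster, held 2.65% and 1.41%. Over all kept cells, CD8 T-like cells made up 18.0% (17.0 to 19.0) against 15.1% (14.1 to 16.1), a ratio of 1.19 (1.08 to 1.31), and NK-like cells 5.29% against 2.63%, a ratio of 2.02. On that base the unresolved phagocyte-like cells (23.1% against 22.6%) and the mononuclear phagocytes together (54.6% against 50.5%) were higher in the TMEM16F KO library, the opposite of their order among leukocyte-like cells. That order rests on cluster 5, which is in the base but not among the phagocytes. Its leading genes against other lineages were C1qb, Lyz2 and C1qa, and it stayed unnamed for its few UMIs. With cluster 5 counted as macrophage-like, the mononuclear phagocytes together were lower in the TMEM16F KO library. When each library was clustered on its own, the NK-like ratio turned to 0.793, as the NK-like cluster of the vector control library then took in 188 cells of the other T-like class beside 126 NK-like cells.

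**Figure D1:**
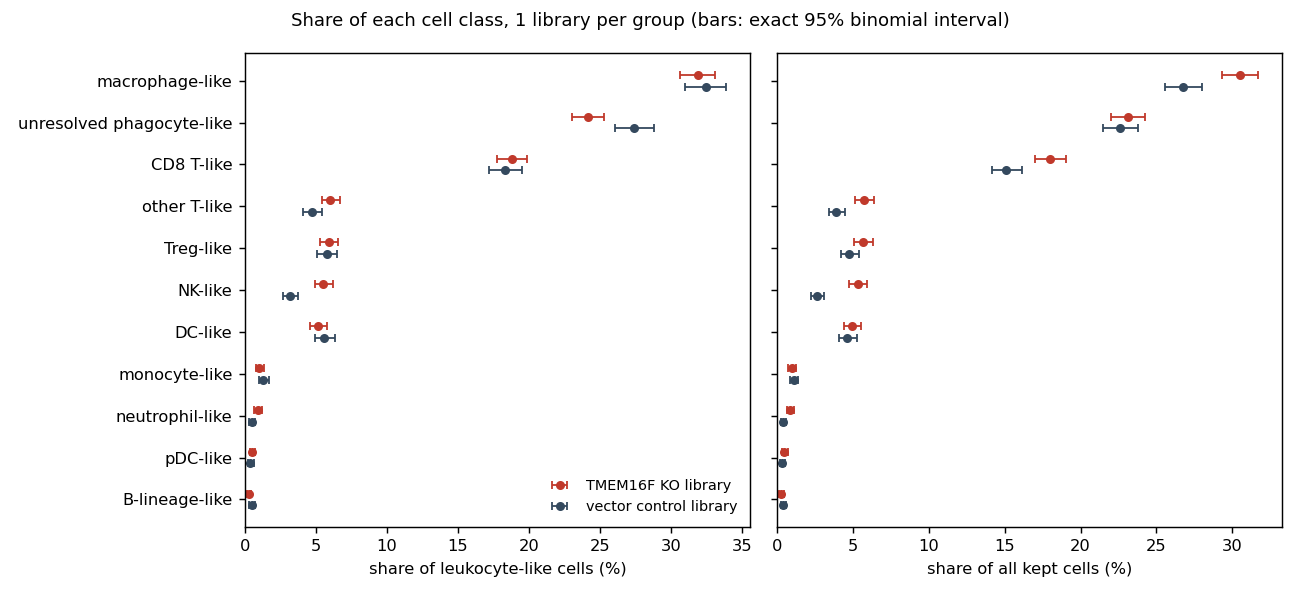
Share of each cell class (x axis, percent) among leukocyte-like cells (left) and among all kept cells (right) in the TMEM16F KO library (red) and the vector control library (dark blue), with bars for exact 95% binomial intervals. NK-like cells lie at 5.52% against 3.18% on the left and at 5.29% against 2.63% on the right, while CD8 T-like cells part only on the right, at 18.0% against 15.1%.

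CD8 T-like cells (1024 TMEM16F KO and 760 vector control cells, median 5285 and 6358.5 UMIs) carried more transcripts of Gzma, Gzmb and some other effector genes in the TMEM16F KO library. Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), a granule protease, stood at 414 against 199 CPM, 2.08-fold higher (1.94 to 2.24). Its UMIs sat in 15.7% against 10.4% of the cells of the class, unthinned. Gzma was higher in the cells outside the class as well, at 182 against 85.6 CPM, so its difference cannot be taken as specific to CD8 T-like cells. Icos, a costimulatory receptor, was 2.06-fold higher at 332 against 162 CPM. Ly6a, an interferon-inducible surface protein, was 2.10-fold higher at 982 against 468 CPM. Serpinb1a, an inhibitor of serine proteases, was 3.48-fold higher (2.52 to 4.89) at 29.8 against 8.57 CPM, and Sgms1, a sphingomyelin synthase, 2.96-fold higher at 44.2 against 14.9 CPM. Ly6a and Sgms1 stood higher still in the cells outside the class, at 1645 and 79.4 CPM in the TMEM16F KO library. The largest difference the other way was in Slc16a11, a monocarboxylate transporter (ENSMUSG00000040938, chromosome 11, 70212752 to 70216417), at 3.48 against 27.2 CPM, 7.80-fold lower (5.01 to 12.7). Lta, the cytokine lymphotoxin alpha, was 2.70-fold lower at 17.6 against 47.4 CPM, and Trgc2, a constant segment of the gamma T cell receptor, 3.19-fold lower. The heat shock genes Hspa1a and Hspa1b were 2.62-fold and 2.39-fold lower. These are near-identical copies, so how their reads divide between them is uncertain.

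Of the cytotoxic effector genes, 12 of 18 measured in CD8 T-like cells were higher and 6 lower in the TMEM16F KO library, with a median log2 ratio of 0.18 (0.15 to 0.26) at the 97.5th percentile of matched lists. The same list was also higher in classes that should lack it, with a median of 0.28 (0.20 to 0.33; 14 of 16 higher) in macrophage-like, 0.57 (0.46 to 0.65; 13 of 14) in unresolved phagocyte-like, 0.86 (0.62 to 1.02; 11 of 14) in DC-like and 2.03 (1.80 to 2.36; 15 of 15) in stroma-like cells. The difference can therefore not be taken as specific to CD8 T-like cells. Stroma-like cells (80 and 99 cells) differed in depth, at medians of 8914 and 20680 UMIs. The size of their list medians, here and below, can hold an effect of that depth. Gzmb stood at 2663 against 1753 CPM, 1.52-fold higher, Ccl5 at 2494 against 1497, and Nkg7 at 3218 against 2738. After thinning, 79.6% (76.7 to 82.3) against 61.6% (57.6 to 65.5) of CD8 T-like cells had a Gzmb UMI (unthinned 76.3% against 65.4%). In macrophage-like cells, which should lack the gene and had median depths of 7654 and 10220.0 UMIs, the thinned share was 7.63% against 7.73%. Naive and stem-like T cell genes were higher for 7 of 8 members, median 0.38 (0.30 to 0.49), among them Satb1 (2.02-fold), Il7r (1.50-fold) and Klf2 (1.31-fold). This list, too, was higher outside T cells, with medians of 0.48 (6 of 7 higher) in NK-like, 0.29 (6 of 7) in unresolved phagocyte-like, 0.33 (5 of 6; -0.23 with classes from single cells) in DC-like and 0.13 (6 of 8) in macrophage-like cells. Exhaustion genes were split, with 8 of 14 higher and a median of 0.13 (-0.01 to 0.22). Lag3, an inhibitory receptor, was 1.30-fold higher and Nr4a2 stood at a ratio of 0.876. Cell cycle genes were lower for 17 of 20, median -0.26 (-0.31 to -0.19, but -0.47 to 0.0068 when whole cells were redrawn), and oxidative phosphorylation genes lower for 14 of 16, median -0.10. After thinning, 14.7% against 22.2% of CD8 T-like cells had UMIs of at least 3 cycling markers (unthinned 17.7% against 26.8%), a ratio of 0.662 (0.515 to 0.852). The cycling cluster 16 held 80 of the TMEM16F KO and 89 of the vector control CD8 T-like cells, and with the clusters weighted alike the cell cycle median was -0.05. Scramblase and flippase genes, the family around TMEM16F, were nearly level, with 7 of 12 higher and a median of 0.08 (-0.04 to 0.13). Dissociation stress genes had a median of 0.05, which turned to -0.0039 without mitochondrial, ribosomal protein and haemoglobin genes.

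NK-like cells (301 and 132 cells, median 5179 and 4952.5 UMIs) of the TMEM16F KO library had more transcripts of granzymes F and G and fewer of histone and other cell cycle genes. Gzmf (ENSMUSG00000015441, chromosome 14, 56205263 to 56211417) stood at 4854 against 1630.1 CPM, 2.98-fold higher (2.82 to 3.15), and its neighbour Gzmg at 2068 against 799 CPM. These paralogs are similar in sequence, so the split between them is uncertain. Gzmf UMIs sat in few cells, 16.2% against 14.1% after thinning (unthinned 16.9% against 11.4%; macrophage-like background 5.06% against 3.18% thinned). Myo10, an unconventional myosin, was 2.95-fold higher, Serpinb9b, a granzyme inhibitor, 3.03-fold higher, and the inhibitory receptor Havcr2 3.61-fold higher (1.93 to 7.49). Havcr2 was also higher in CPM in the cells outside the class than in NK-like cells of the same library. Rrm2, a subunit of ribonucleotide reductase, was 4.06-fold lower at 19.1 against 77.7 CPM. The histone genes H2ac8, H2ac4, H2ac24 and H1f5 were 3.90-, 6.78-, 3.68- and 3.45-fold lower. UMIs of Rrm2 and the histone genes also sat in few cells. Unthinned shares were 6.64% against 9.85% for Rrm2, 2.33% against 7.58% for H2ac4 and 11.6% against 18.9% for H2ac24. They were 9.30% against 6.06% for Gzmg and 7.97% against 6.06% for Serpinb9b, so these fold values rest on few cells. Histone genes have near-identical copies, so the values of single copies are uncertain in every class.

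Across the lists, cytotoxic effector genes in NK-like cells went both ways, 9 of 17 higher and 8 lower with a median of 0.04 (-0.03 to 0.14). Gzmd stood 1.48-fold higher, while Gzmc (10532.5 against 13668.5 CPM) and Xcl1 (2463 against 3795 CPM) had ratios of 0.771 and 0.649. The thinned share of cells with a UMI was 60.0% against 66.3% for Gzmc and 83.8% against 91.3% for Xcl1 (unthinned 48.2% against 55.3% and 79.1% against 86.4%). In macrophage-like cells the thinned shares were 5.21% against 5.10% for Gzmc and 4.77% against 5.91% for Xcl1. Cell cycle genes were lower for 17 of 17, median -0.84 (-1.04 to -0.72; redrawn cells -1.47 to -0.22), as in Hmgb2 (441 against 914 CPM) and Pclaf (89.0 against 251 CPM). Exhaustion genes had 9 of 13 members higher, median 0.21 (0.05 to 0.39), with 4 of 13 above their intervals. Classes that are neither T nor NK cells had medians of 0.10 (9 of 13 higher, macrophage-like), 0.24 (9 of 10, unresolved phagocyte-like), 0.48 (10 of 10, DC-like; -0.25 with classes from single cells) and 0.68 (6 of 6, stroma-like). The difference can therefore not be taken as specific to NK-like cells. In NK-like cells dissociation stress genes had a median of -0.01. The fixed NK cell markers were close to level between the libraries, with a median of -0.056 (-0.11 to 0.010).

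Treg-like cells (322 and 239 cells, median 3255 and 3444 UMIs) kept their suppressor genes near level while a few other genes, Xcl1 and Il7r among them, stood higher in the TMEM16F KO library. Suppressor genes were higher for 11 of 17, median 0.08 (-0.02 to 0.13), with Tnfrsf4 1.31-fold and Ctla4 1.06-fold higher. Xcl1, a chemokine for cross-presenting dendritic cells (ENSMUSG00000026573, chromosome 1, 164931644 to 164935527), was 5.36-fold higher (3.85 to 7.63) at 185 against 34.5 CPM. The receptor of interleukin 7, Il7r, was 2.45-fold higher at 352 against 144 CPM. Upp1, Klrc1 and Fosb were 2.60-, 2.53- and 2.18-fold higher. Xcl1, Upp1, Klrc1 and Fosb all had more CPM in the cells outside the class (334, 157, 114 and 355 CPM in the TMEM16F KO library). Naive and stem-like genes were higher for 5 of 7, median 0.57 (0.25 to 0.66), which came to 0.07 as a mean over cells. Cytotoxic effector genes had a median of 0.20 (0.08 to 0.41). All 20 cell cycle genes were lower, median -0.52 (-0.62 to -0.41), and Cenpf, a kinetochore protein, was 2.68-fold lower. Hspa1b and Hspa1a were 3.11- and 2.44-fold lower, H2ac24 2.50-fold and H3c3 2.68-fold, while dissociation stress genes as a list had a median of 0.25 (-0.10 as a mean over cells).

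MHC class II genes, which present antigen to CD4 T cells and are products of phagocytes, dendritic cells and B cells, were higher in CD8 T-like, NK-like and Treg-like cells of the TMEM16F KO library and near level in other T-like cells. The median log2 ratio was 1.02 (0.94 to 1.14; 9 of 10 higher) in CD8 T-like, 1.14 (0.99 to 1.25; 8 of 8) in NK-like and 0.72 (0.65 to 0.96; 8 of 8) in Treg-like cells. In CD8 T-like cells Cd74 stood at 996 against 349 CPM and H2-Aa at 634 against 254 CPM. Macrophage markers that T cells do not make were higher beside them. In CD8 T-like cells C1qa stood at 277 against 140.4 CPM (1.98-fold), Apoe at 340 against 103 (3.29-fold) and Lyz2 at 1229 against 429 (2.87-fold). The 12 macrophage markers summed were 2.18-fold higher in CD8 T-like, 1.96-fold in NK-like and 1.60-fold in Treg-like cells. In other T-like cells the MHC class II median was 0.045 (-0.0017 to 0.22; 6 of 8 higher), with Cd74 at a ratio of 1.05, and the summed macrophage markers at 1.11 (1.03 to 1.19), with C1qb at 0.939 and C1qc at 0.871. With classes drawn from the marker UMIs of single cells, the MHC class II median turned to -1.28 in NK-like cells and came to 1.53 in other T-like cells, where the summed macrophage markers were then 2.42-fold higher (2.19 to 2.69). A cell entered these classes only if its own markers led those of phagocytes, so they were picked partly by the transcripts compared here.

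**Figure D2:**
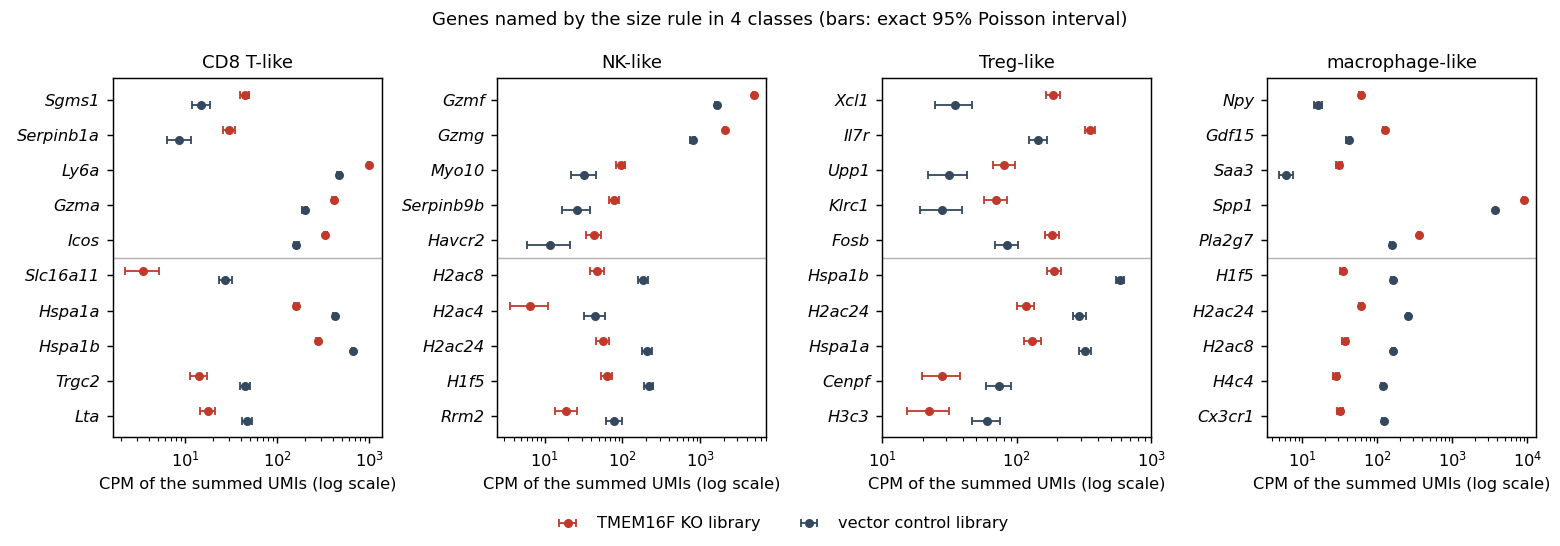
CPM of the summed UMIs (x axis, log scale) of the genes named by the size rule in CD8 T-like, NK-like, Treg-like and macrophage-like cells, in the TMEM16F KO library (red) and the vector control library (dark blue), with bars for exact 95% Poisson intervals. Genes above the grey line were higher and genes below it lower in the TMEM16F KO library, as with Xcl1 in Treg-like cells (185 against 34.5 CPM) and H1f5 in macrophage-like cells (34.9 against 161 CPM).

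Macrophage-like cells (1736 and 1346 cells, median 7654 and 10220.0 UMIs) of the TMEM16F KO library had more transcripts of lipid-associated and suppressor genes and fewer of cell cycle genes. Spp1, the secreted phosphoprotein osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), stood at 8921 against 3734 CPM, 2.39-fold higher (2.37 to 2.41). Gdf15, a stress-induced cytokine, was 3.01-fold higher at 126 against 41.9 CPM, Npy, neuropeptide Y, 3.78-fold at 61.5 against 16.3, the acute phase protein Saa3 5.08-fold, and Pla2g7, a phospholipase, 2.30-fold. Cx3cr1, the fractalkine receptor (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), was 3.83-fold lower (3.48 to 4.22) at 32.0 against 123 CPM. The histone genes H1f5, H2ac24, H2ac8 and H4c4 were 4.62-, 4.18-, 4.42- and 4.22-fold lower. The makeup of the class differed, since its cycling cluster 13 held 57 TMEM16F KO and 188 vector control cells and its cluster 7, with a median of 3025 UMIs, held 401 and 197. Without cluster 13, 5 of the 10 named genes were named again.

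By list, lipid-associated macrophage genes were higher for 10 of 11, median 0.42 (0.40 to 0.47), as in Apoe (1.49-fold), Ctsb (1.34-fold) and Lgals3 (1.30-fold), and MDSC suppressor genes for 16 of 18, median 0.41 (0.36 to 0.46), as in Wfdc17 (2.13-fold) and Cebpb (1.39-fold). Neither difference can be taken as specific to macrophage-like cells. The lipid-associated median was 0.64 in CD8 T-like, 0.66 in NK-like, 0.76 in Treg-like and 1.06 in stroma-like cells. The MDSC suppressor median was 0.51, 0.60, 0.31 and 1.06 in the same order. In those classes, free RNA in the droplets was not excluded as the source. With the clusters weighted alike in both libraries the lipid-associated median was 0.24. MHC class I genes (13 of 16 higher, median 0.22), type I interferon response genes (20 of 22, median 0.21), interferon gamma response genes (15 of 19, median 0.21) and inflammatory NF-kB genes (18 of 20, median 0.21) were moderately higher. Within the interferon gamma list the T cell attracting chemokines Cxcl9 (606 against 938 CPM) and Cxcl10 (919 against 1223 CPM) were lower, at ratios of 0.646 and 0.751. After thinning, 40.9% against 51.1% of cells had a Cxcl9 UMI and 51.1% against 59.2% a Cxcl10 UMI (unthinned 51.0% against 59.0% and 63.8% against 71.2%). The thinned shares in CD8 T-like cells, the background here (median 5285 and 6358.5 UMIs), were 11.7% against 9.88% and 26.2% against 26.0%. Chemokine genes as a list had a median near 0, at 0.06 (-0.02 to 0.11), over members that went both ways, with Cxcl2 1.46-fold higher and Ccl4 at a ratio of 0.774.

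In macrophage-like cells, cell cycle genes were lower for 20 of 20, median -0.99 (-1.03 to -0.90), among them Hmgb2 (240.5 against 542 CPM), Stmn1 (211 against 445) and Pclaf (72.1 against 230.2). Without cluster 13 the median was -0.45, and with the clusters weighted alike -0.13. Oxidative phosphorylation genes were lower for 16 of 16, median -0.23 (-0.25 to -0.19), as in Cox5b at a ratio of 0.776. MHC class II genes were lower for 10 of 12, median -0.11 (-0.13 to -0.07), a direction that turned to 0.060 with the clusters weighted alike. Genes for binding and engulfing cells that expose phosphatidylserine, the lipid TMEM16F moves, went both ways, with 8 of 15 higher and a median near 0, at 0.10 (0.01 to 0.17). The lipid exporter Abca1 was 1.67-fold higher and Rac1 stood at a ratio of 0.906. With the clusters weighted alike this median was -0.012. Scramblase and flippase genes had a median of 0.13 and hypoxia genes of 0.12 (15 of 18 higher), the latter turning to -0.086 as a mean over cells, and dissociation stress genes of 0.01.

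Unresolved phagocyte-like cells (1315 and 1138 cells, median 7483 and 8278.5 UMIs) had a larger median of type I interferon response genes than macrophage-like cells. That list was also higher in monocyte-like cells and, except with classes from single cells, in DC-like cells. They consist of cluster 0 (864 and 814 cells), led by Il1b, Osm and Cd14 with the neutrophil markers Il1r2 and Trem1 among its leading genes, and cluster 3 (451 and 324 cells), led by Ccr2. The class was added to the named genes after the data had been seen. Type I interferon response genes were higher in the TMEM16F KO library for 22 of 22, median 0.59 (0.51 to 0.66), as in Isg15 (632 against 372 CPM, 1.70-fold) and Ifitm3 (1.57-fold). Ifitm1, a membrane protein of the same family, was the gene with the largest ratio on the ranking scale, 3.26-fold higher at 1691 against 519 CPM. It was higher in the cells outside the class as well, at 710 against 475 CPM. Ccl5 was 2.48-fold higher at 646 against 260.0 CPM, Inhba, a subunit of activin, 2.62-fold, and Gdf15 stood at 40.6 against 13.1 CPM. Ccl5 and Gdf15 stood higher in the cells outside the class, at 1242 and 74.8 CPM in the TMEM16F KO library. Aldh1l1, a folate enzyme, was 15.4-fold higher (9.16 to 28.0) at 20.7 against 1.34 CPM. Cx3cr1 was 3.21-fold lower here too, Qpct 2.40-fold, Gatm, an enzyme of creatine synthesis, 2.14-fold at 179.7 against 384 CPM, Fgf13 2.66-fold and Ccl17 2.45-fold.

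The remaining lists in these clusters mostly stood higher. MHC class I genes were higher for 15 of 16 (median 0.27), interferon gamma response genes for 17 of 19 (0.29), inflammatory NF-kB genes for 18 of 20 (0.28), MDSC suppressor genes for 13 of 17 (0.26), chemokine genes for 13 of 21 (0.17), lipid-associated genes for 8 of 10 (0.17) and MHC class II genes for 8 of 12 (0.12). Cell cycle genes were lower for 18 of 20, median -0.30 (-0.38 to -0.24), and oxidative phosphorylation genes for 15 of 16, median -0.12. The thinned share of cells with at least 3 cycling markers was 1.54% against 4.31% (unthinned 4.33% against 12.3%), a ratio of 0.357 (0.186 to 0.655). Efferocytosis genes had a median of -0.02, hypoxia genes of 0.11, which turned to -0.12 with classes from single cells, and dissociation stress genes of 0.11.

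**Figure D3:**
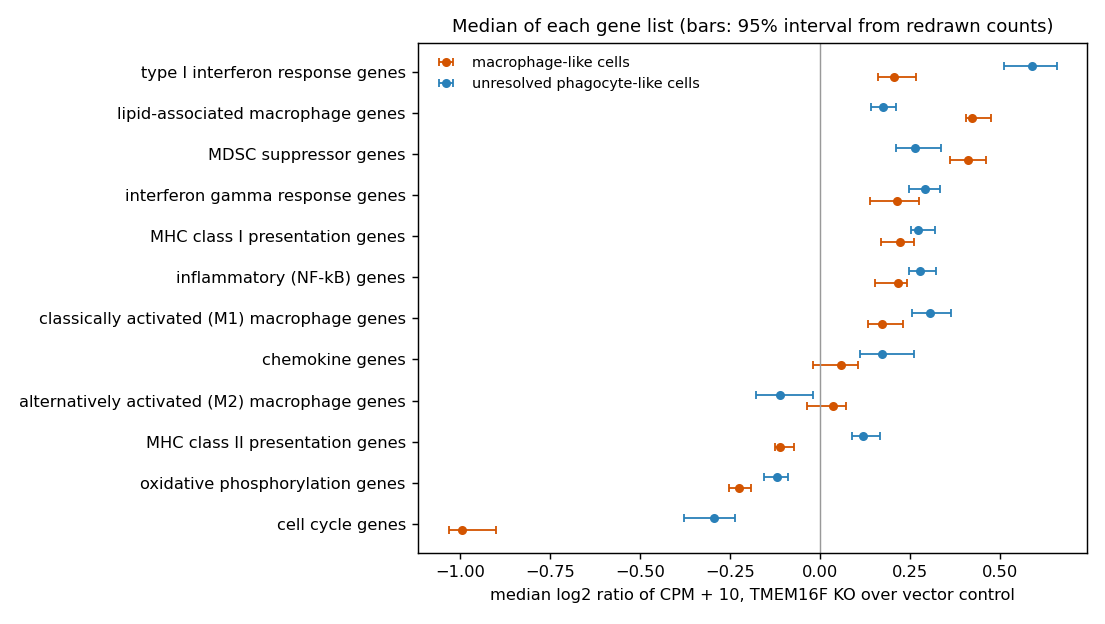
Median log2 ratio of CPM + 10, TMEM16F KO over vector control (x axis), of 12 gene lists in macrophage-like (orange) and unresolved phagocyte-like (blue) cells, with bars for 95% intervals from redrawn counts. Type I interferon response genes lie furthest right in unresolved phagocyte-like cells (0.59) and cell cycle genes furthest left in macrophage-like cells (-0.99).

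The balance of classically activated (M1) and alternatively activated (M2) macrophage genes was nearly the same in macrophage-like cells of the libraries and leaned to M1 in unresolved phagocyte-like cells of the TMEM16F KO library. In macrophage-like cells the 16 measured M1 genes summed to 4411 CPM (4380 to 4443) against 4366 (4333 to 4400) and the 17 M2 genes to 4496 against 4381. The log2 ratio of M1 over M2 was -0.03 against -0.005, a difference of -0.02 (-0.04 to -0.0005). In unresolved phagocyte-like cells the M1 sum was 8437 CPM against 6473 and the M2 sum 2800 against 3386, a difference of 0.66 (0.63 to 0.68) in the log2 ratio. This difference came to 0.21 with classes from single cells and to 0.36 without the gene with most UMIs of each list. There Il1b stood at 3849 against 2735 CPM and the M2 gene Arg1, arginase, at 1444 against 1964 CPM. In CD8 T-like cells, which should lack both, thinned shares were also higher, at 21.4% against 12.5% for Il1b and 26.6% against 16.0% for Arg1. The higher Il1b can therefore not be taken as specific to these phagocytes. It is not shown to be shared either, as free RNA in the droplets was not excluded as its source in CD8 T-like cells. As a list, M1 genes had a median of 0.17 (0.13 to 0.23; 11 of 16 higher) in macrophage-like and 0.30 (0.26 to 0.36; 13 of 17 higher) in unresolved phagocyte-like cells. The M2 medians were 0.03 (-0.04 to 0.07) and -0.11 (-0.18 to -0.02), the latter turning to 0.0035 under the stricter cell filter. In macrophage-like cells Ccl5 was 1.86-fold and Il1b 1.19-fold higher, Arg1 1.06-fold higher and Mrc1 at a ratio of 0.971. After thinning, 53.6% against 46.8% of macrophage-like cells had an Il1b UMI (unthinned 65.1% against 64.0%; CD8 T-like background 21.4% against 12.5% thinned), 83.2% against 82.6% an Arg1 UMI (unthinned 81.3% against 86.4%; background 26.6% against 16.0%) and 48.8% against 51.3% an Mrc1 UMI (unthinned 67.8% against 71.4%; background 4.19% against 2.14%). The small difference in macrophage-like cells had the opposite sign without the cycling cluster (0.21) and with the clusters weighted alike (0.32).

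**Figure D4:**
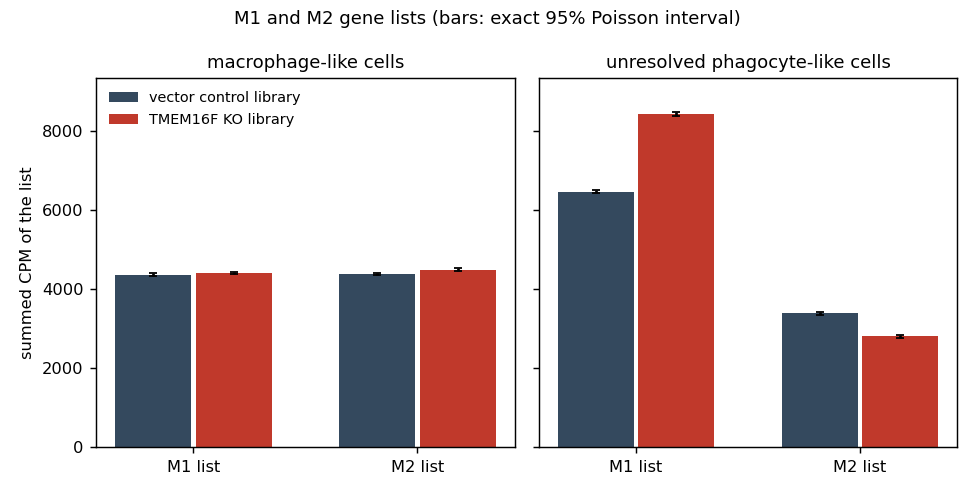
Summed CPM (y axis) of the M1 and M2 gene lists in macrophage-like (left) and unresolved phagocyte-like (right) cells of the vector control library (dark blue) and the TMEM16F KO library (red), with bars for exact 95% Poisson intervals. The left panel is nearly level, at 4411 against 4366 CPM for M1, while on the right M1 stands at 8437 CPM in the TMEM16F KO and 6473 CPM in the vector control library.

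Monocyte-like cells (55 and 54 cells, median 4611 and 4242.5 UMIs) of the TMEM16F KO library had more transcripts of MHC class II genes and, in a few cells, of the neutrophil genes S100a8, S100a9 and Lcn2. MHC class II genes were higher for 8 of 8, median 1.08 (0.84 to 1.37). This is about as much as in CD8 T-like (1.02) and NK-like cells (1.14), which do not make them, so free RNA stays open here as well. Stroma-like cells, of unlike depth in the 2 libraries, had a median of 1.06. H2-Aa stood at 2321 against 588 CPM (3.95-fold, 3.29 to 4.77), below the 4493 CPM of the cells outside the class in the TMEM16F KO library. S100a9, a calcium-binding neutrophil protein, had 495 UMIs against 0 and was at least 129.7-fold higher at a floor of 3 counts, and its partner S100a8, with 745 UMIs against 5, was 117-fold higher. Their UMIs sat in 5.45% and 7.27% of the TMEM16F KO cells and those of Lcn2 in 5.45%, all unthinned. Stmn1 stood at 208 against 12.6 CPM, the latter from 3 UMIs, a ratio of 16.5 (5.40 to 82.2), beside 231 CPM outside the class in the TMEM16F KO library. Hspa1b and Hspa1a were 3.04- and 2.94-fold lower, the integrin Itga4 3.22-fold, Aplp2 2.47-fold and the transcription factor Hes1 2.37-fold. MDSC suppressor genes were near level, median 0.05 (-0.14 to 0.17), and 6 of 8 type I interferon response genes were higher, median 0.41 (0.09 to 0.60).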

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

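No paired analysis was possible because each group has 1 library. Of the main results recomputed under other settings, 126 values lay within the 95% interval of the reported value or, for genes named again and lists that kept their direction, within 1.5 times of the full number, 48 lay outside it, and 11 changed side where the reported interval excluded no difference. Among shares whose reported interval includes 1, ratios lay on both sides for macrophage-like (0.790 to 1.15) and monocyte-like cells (0.622 to 1.29). Those of CD8 T-like (1.03 to 1.20) and Treg-like cells (1.03 to 1.28) stayed above 1 wherever a ratio was given. Under each setting 78.9% to 100% of the described gene lists kept their direction. None of the single named genes turned direction. A minimum of 2000 UMIs per cell, counting cluster 5 as macrophage-like, leaving out the cycling cluster, weighting clusters alike and leaving out the gene with most UMIs were chosen after seeing the data. Except where the reason is given, the cause of a difference was not tested.

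The ratio of the NK-like share (1.74) stayed above 1 in every setting but 1, with 2.03 as its highest value. It was 0.793 with each library clustered on its own, because the NK-like cluster of the vector control library then took in 188 cells of the other T-like class. Own clustering gave no monocyte-like ratio and no Treg-like ratio, the latter as the Treg-like cells of the TMEM16F KO library fell in an unnamed cluster. Thinning cells before clustering gave no Treg-like ratio either. The neutrophil-like ratio kept between 1.85 and 2.50.

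The ratio of the CD8 T-like share (1.03) was 1.19 over all kept cells, 1.16 at double the doublet rate, 1.20 with 1000 variable genes, 1.17 with own clustering, 1.20 with classes from single cells, 1.18 with cells thinned before clustering and 1.17 with cluster 5 as macrophage-like. The Treg-like ratio (1.03) was 1.28 with 1000 variable genes and 1.27 with classes from single cells, and the monocyte-like ratio (0.776) was 1.29 with 1000 variable genes. The macrophage-like ratio (0.982) was 1.14 over all kept cells, 0.899 with at least 500 genes and under 10% mitochondrial UMIs, 0.812 at double the doublet rate, 0.902 at resolution 2, 0.862 with 1000 variable genes, 1.15 with own clustering, 0.899 with classes from single cells, 0.863 with thinned cells and 0.790 with cluster 5 included.

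The ratio of unresolved phagocyte-like cells (0.880) was 1.02 over all kept cells, as unnamed cells were more frequent in the vector control library, 0.716 at resolution 0.5, 0.964 at resolution 2, 0.802 with own clustering and 1.003 with cluster 5 as macrophage-like. The ratio of mononuclear phagocytes together (0.932) was 1.08 over all kept cells, 0.883 with the stricter filter, 0.866 at double the doublet rate, 0.874 with thinned cells, 0.987 among cells with at least 2000 UMIs and 0.868 with cluster 5 included. The Ano6 ratio (1.16) was 0.856 in cells with at least 2 tumour markers and 1.07 as a share of cells with a UMI after thinning.

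Of the 10 named genes of a class, a mean over cells named 5 again in CD8 T-like, 3 in NK-like, 4 in Treg-like and 6 in macrophage-like cells. A pseudocount of 1 CPM named 6 again in NK-like, 6 in Treg-like and 5 in macrophage-like cells, and 50 CPM named 6 in CD8 T-like and 6 in NK-like cells. Classes from single cells named 5 again in NK-like, 2 in Treg-like and 2 in monocyte-like cells. In monocyte-like cells a minimum of 10 UMIs named 3 again and the stricter filter 5. In macrophage-like cells leaving out the cycling cluster named 5 again, as did weighting the clusters alike (5).

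Among the gene lists, the cell cycle median in other T-like cells (-0.46) was 0.043 with classes from single cells, and the M2 median in unresolved phagocyte-like cells (-0.11) was 0.0035 with the stricter filter. The MHC class II median in macrophage-like cells (-0.11) was 0.021 with classes from single cells, 0.0015 without the cycling cluster and 0.060 with clusters weighted alike, and that in NK-like cells (1.14) was -1.28 with classes from single cells. The efferocytosis median in macrophage-like cells (0.10) was -0.012 with clusters weighted alike. The hypoxia median in macrophage-like cells (0.12) was -0.086 as a mean over cells and -0.029 with clusters weighted alike, and in unresolved phagocyte-like cells (0.11) it was -0.12 with classes from single cells. The dissociation stress median in CD8 T-like cells (0.05) was -0.0039 without mitochondrial, ribosomal protein and haemoglobin genes, and in Treg-like cells (0.25) it was -0.10 as a mean over cells. With classes from single cells the medians in DC-like cells of type I interferon (0.35), naive (0.33) and exhaustion genes (0.48) were -0.027, -0.23 and -0.25.

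The M1 and M2 balance of macrophage-like cells (-0.02) was 0.20 as a mean over cells, 0.24 with classes from single cells, 0.036 with the stricter filter, 0.21 without the cycling cluster, 0.32 with clusters weighted alike and 0.21 without the gene with most UMIs of each list. In unresolved phagocyte-like cells (0.66) it was 0.61, 0.21, 0.53 and, without the gene with most UMIs, 0.36.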

Other observations

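Aldh1l1 and Hspa1b differed in the same direction in classes beyond those described for them above, and these comparisons, like those of Ifnb1, were chosen after the values had been seen. Aldh1l1, an enzyme of folate metabolism, was higher in the TMEM16F KO library in macrophage-like cells (12.6 against 1.76 CPM, 7.15-fold, 4.78 to 11.1) as well as in unresolved phagocyte-like cells. In DC-like cells it was 24.2-fold higher (6.41 to 204) with 2 UMIs in the vector control library. In Treg-like cells it had 21 UMIs against 0, at least 5.61-fold at a floor of 3 counts. The inducible heat shock gene Hspa1b was lower in DC-like cells (265 against 863 CPM) and macrophage-like cells (123 against 264 CPM), as in the lymphoid classes, while stroma-like cells were level at a ratio of 0.893 (0.794 to 1.002).

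DC-like cells, led by Ccl17, Ccl22 and Ccr7, had fewer transcripts of interferon beta in the TMEM16F KO library. Their cell cycle median was above 0, while those of T-like, NK-like and macrophage-like cells were below 0, but no test compared the classes. Ifnb1 stood at 11.5 CPM (33 UMIs) in the TMEM16F KO library and at 105 CPM (246 UMIs) in the vector control library, a ratio of 0.110 (0.0741 to 0.159). In macrophage-like cells it was lower as well, at 25.9 against 71.9 CPM, and the macrophage-like cluster 11, with Ifnb1 among its leading genes, held 214 and 242 cells. The lower Ifnb1 transcripts stand beside type I interferon response genes that were higher in unresolved phagocyte-like cells. In DC-like cells themselves these response genes were also higher, for 18 of 19, median 0.35 (0.23 to 0.47), which came to -0.027 with classes from single cells. In DC-like cells, cell cycle genes were higher for 18 of 20, median 0.27 (0.16 to 0.36, but -0.21 to 0.72 when whole cells were redrawn), with Stmn1 1.24-fold and Pclaf 1.33-fold higher, while the share of cycling cells was 9.21% against 8.90% after thinning. The redrawn interval overlaps those of CD8 T-like (-0.47 to 0.0068), Treg-like (-0.99 to -0.12) and other T-like cells (-0.92 to -0.038). It does not overlap those of NK-like (-1.47 to -0.22) and macrophage-like cells (-1.17 to -0.74). Oxidative phosphorylation genes were lower in DC-like cells for 15 of 16, median -0.16.

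The NK-like share was higher in the TMEM16F KO library, and of its tests, those of cells with at least 2000 UMIs, of the joint share and of the count of libraries were chosen only after the result was seen, while classes from single cells were fixed beforehand and only their use to test the border came after. Among all cells with at least 2000 UMIs the NK-like share was 5.41% against 2.80%, a ratio of 1.93 (1.54 to 2.43), which rules out barcodes of few UMIs as the cause. NK-like and other T-like cells together made up 11.5% against 7.90% of leukocyte-like cells, a ratio of 1.46 (1.27 to 1.67), which a border between these clusters cannot change, so it does not account for the higher share of both together. For NK-like cells alone the border stays open. Against it, the ratio with classes from single cells was 1.62 (1.23 to 2.15; 2.90% against 1.79%), but with each library clustered on its own it was 0.793 (0.675 to 0.930), which goes with it. With 1 library per group, a response to the lost TMEM16F and a difference between tumours or cell preparations cannot be told apart.

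Macrophage and MHC class II transcripts were higher in CD8 T-like, NK-like and Treg-like cells of the TMEM16F KO library, and the tests in other T-like cells and of MHC class II genes switched on in CD8 T-like cells were chosen only after the result was seen. Leaving out the top 10% of CD8 T-like cells by these markers kept the ratio at 1.82 (1.73 to 1.91; 848 against 466 CPM), which argues against doublets. The 12 macrophage markers, which are not MHC genes, were 2.18-fold higher (2.09 to 2.27). MHC class II genes switched on in the T cells would leave these markers unexplained. As the markers belong to the pattern itself, they cannot decide whether MHC class II genes were switched on there as well. Free RNA in the droplets stays open, as the middle ratio of the markers relative to phagocytes was 2.02 in CD8 T-like, 1.95 in NK-like and 1.49 in Treg-like cells, within 1.36 times of each other. The summed markers of other T-like cells stood at a ratio of only 1.11 (1.03 to 1.19), which would speak against it as the whole cause. With classes from single cells that ratio was 2.42 (2.19 to 2.69), above those of the other lymphoid classes. That value is no recheck of the first, as its 229 and 132 cells are another set than the 327 and 196 of the cluster. They were also picked partly by having fewer of the same macrophage markers. Free RNA as the whole cause therefore stays open too.

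Cell cycle genes were lower in most classes of the TMEM16F KO library, and the tests of UMIs per cell in NK-like and Treg-like cells and that of genes outside the cycling markers were chosen only after the result was seen. After thinning, 8.36% against 24.3% of macrophage-like cells had UMIs of at least 3 cycling markers (unthinned 13.2% against 34.8%), a ratio of 0.344 (0.274 to 0.430), so UMIs per cell do not account for the difference in this class. In NK-like cells the cell cycle median after thinning was -0.65, narrowly below 0 when cells were redrawn (-1.21 to -0.015), which argues against UMIs per cell as the whole cause, but thinning the same cells moved it by 0.32 (-0.072 to 0.70; ratio of cycling cells 0.836, 0.385 to 1.92), so they stay open as a large part of it. In Treg-like cells, with -0.38 (-0.86 to 0.073), a move of 0.087 (-0.19 to 0.41) and a ratio of 0.813 (0.491 to 1.35), the cells were too few to exclude them even as the whole cause. In NK-like cells the NK cell markers had a median log2 ratio of -0.056 (-0.21 to 0.12 for redrawn cells), above the level that a dilution by free macrophage RNA would need. Macrophage-like cells with fewer than 3 cycling markers had a cell cycle median of -0.15 (-0.20 to -0.046; 17 genes), and for the genes outside the cycling markers it was -0.066 (-0.17 to 0.0061; 8 genes) beside -0.75 in all macrophage-like cells (10 genes), but these cells were picked by cell cycle markers, so fewer cycling cells and a lower level per cell stay unseparated, and no biological explanation was tested.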
